A study of Mus musculus with 4 samples.

How the data were processed

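Thymic invariant natural killer T (iNKT) cells were profiled by RNA sequencing in 4 libraries. They are T cells whose alpha-beta receptor has a nearly fixed alpha chain and recognises lipids held by CD1d. There were 2 libraries from wild-type (WT) mice and 2 from mice lacking the SLAM family receptors (SFR KO), on the C57BL/6 background per the labels. Groups were taken from the genotype labels. Per the series' design text, thymocytes were depleted of cells carrying CD11b, CD11c, Gr-1, Ter-119, CD19 or CD8a, and cells binding the CD1d tetramer and a TCR antibody were then sorted. Libraries were made with a stranded TruSeq mRNA kit per the series' design text, whereas the labels' protocols name the TruSeq RNA system, and were sequenced as paired ends on an Illumina HiSeq per the labels' protocols.

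Reads were checked with FastQC 0.10.1 and aligned with TopHat 2.0.10 to GRCm38 per the series' design text. CASAVA 1.8, featureCounts 1.4 and DESeq2 1.4.5 are named per the submitters' processing notes, with no role or order. The annotation release and the strand setting of the counting were not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart with certainty. The deposited signal values were gene counts that the authors had divided by 1 size factor per library, for 41214 genes. Every value was a whole multiple of 1 step per library, so the read counts were recovered, and 100% of values came out whole within 0.001. The steps matched median-of-ratio size factors computed from the recovered counts. The authors' deposited table also held a mean signal per gene, a log2 fold change with its standard error on the log2 scale, a score (the fold change over its standard error), and a p-value with its adjusted p-value. Columns of other series numbered 0.

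Recovered reads in genes numbered 52602830 and 46251903 in the WT libraries and 55284185 and 45215986 in the SFR KO libraries. Within each group the libraries differed by more than sampling noise, with a chi-square per degree of freedom of 30.6 for WT and 26.7 for SFR KO, so neither pair was the same counts deposited again; this does not show that they are biological replicates. The titles carry different numbers within each group, and 1 number is shared between the groups, but they do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries. Counting intervals are exact 95% intervals and cover counting error only.

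The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) on log2(value + 1), for the 13631 genes with a mean value of at least 10 over the 4 libraries. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 were called. Fold changes are SFR KO over WT on the log2(value + 1) scale, which understates the change of low genes. The quasi-likelihood test of edgeR 4.0.16 on the recovered reads called 1475 genes, and DESeq2 1.42.0 on the same reads was a further alternative. Gene coordinates came from GENCODE M21 on GRCm38, in which 40254 of the gene identifiers were found.

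The design, the alternatives and 28 gene lists were fixed before the data were examined. Of these lists, the targeted genes and the sex-linked genes were reported by value, and the erythroid list had fewer than 3 tested members. The other 25 were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. They were tested again with an estimated correlation and with fry. Camera with an estimated correlation rests on the few residual degrees of freedom of the 4 libraries. A call lost in that setting need not reflect correlated genes. Targeted genes were left out of the other lists. Named genes were the targeted genes, the 13 called genes with the largest fold change in each direction, the 4 members of each list with the smallest p, 5 sex-linked genes, and 12 genes named in advance. The 13 per direction were taken outside the targeted and sex-linked lists, with both SFR KO values on 1 side of both WT values, a mean of at least 50 in the higher group and a symbol that is not predicted. Alternatives were pseudocounts of 0.5 and 5, filters at means of 1 and 50 or none, TMM and quantile scaling, eBayes without trend or robust, both count tests, and leaving out each library in turn. Lists without shared or near-identical members were added after the data were seen.

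The tests were run on simulated data with known answers, with counts drawn for the 13631 genes at the libraries' depths and 100 genes changed at each of 2 fold sizes. Over 10 draws with gene-wise spread, limma recovered on average 77.5% of genes changed 2-fold and 41.6% of those changed 1.5-fold. Unchanged genes made up 12.7% of its calls on average (4.27% to 18.5% per draw), above the nominal 5%. They made up 13.4% for edgeR and 12.7% for DESeq2. With a spread that followed the mean alone, a setting added after this excess was seen, they made up 3.56% of limma's calls. Each draw changed 100 genes per fold size and a further set of 25, far fewer than the 1381 genes limma called in the data. These shares therefore need not hold for those calls.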

Results

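Gene expression was measured by RNA sequencing in thymic iNKT cells sorted from WT and SFR KO mice, with 2 libraries per genotype. SFR is read here as the SLAM family receptors, a group of surface receptors of haematopoietic cells, several of which signal through the adaptor SAP, encoded close together on chromosome 1. Reads in genes ranged from 45215986 to 55284185 per library. Mitochondrial transcripts made up 2.03% to 2.52% of them. The comparison asked how the loss of these receptors alters gene expression in iNKT cells.

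The targeted genes were measured first in every library. All 7 were expressed in WT and nearly without reads in SFR KO, over a stretch of chromosome 1 from 171559193 to 171953170 (GRCm38). Ly9 had 21383 and 18598 reads in the WT libraries and 4 and 13 in the SFR KO libraries. Cd84 had 8546 and 7319 reads against 8 and 6, and Slamf6 had 2381 and 2439 against 1 and 3. Cd48 and Slamf7 each had 0 reads in SFR KO replicate 1 and 4 in SFR KO replicate 2, against 12360 and 7817 reads over the WT libraries. Slamf1 had 3 reads over both SFR KO libraries, or 0.324% of its WT level (counting interval 0.0638% to 0.908%). Cd244, whose annotated span overlaps Ly9, kept 3.29% of its WT level (2.28% to 4.55%), with 17 and 19 reads. Each of the 7 genes was lower in limma, with adjusted p from 4.1e-08 to 0.00012. Gm10521, a gene between Cd84 and Slamf6 named after its values were seen, had normalized counts of 252 and 208 in WT and 0 reads in SFR KO, at least 158-fold lower at a floor of 3 reads over the group.

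**Figure D1:**
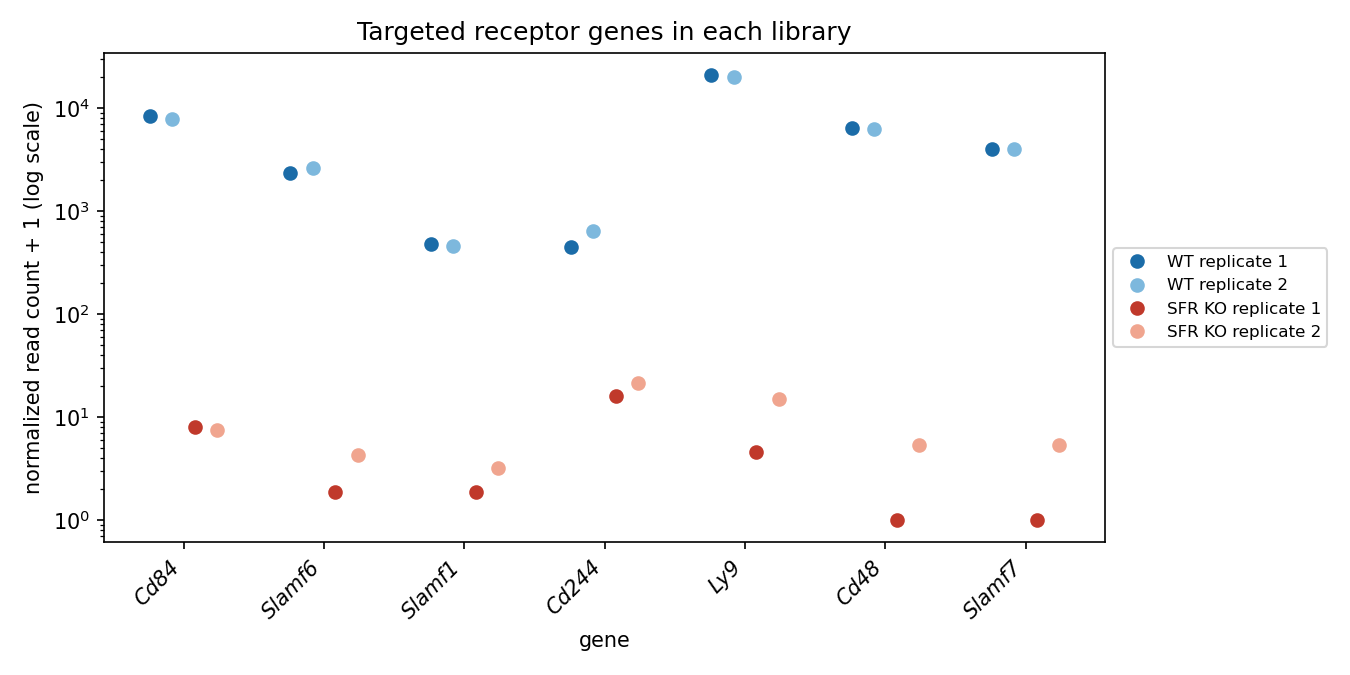
Normalized read count + 1 (vertical log axis) of the 7 targeted genes (horizontal axis), 1 point per library. The WT points of Ly9 lie at 20793 and 19981 normalized counts, and the SFR KO points of all genes lie at 20.6 or less.

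The libraries also differed in sex-linked transcripts. Xist, the RNA that silences an X chromosome in female cells, had 9664.9 normalized counts in SFR KO replicate 1 and 3.3 or less in each other library. The Y-linked gene Ddx3y had 2.6 in that library against 3436.4 and 3030.7 in WT and 2929.2 in SFR KO replicate 2. Eif2s3y and Uty had 0.9 each in SFR KO replicate 1 and at least 785.3 elsewhere. Kdm5d had 54.7 there and at least 2392.1 elsewhere. The title of SFR KO replicate 1 ends in f and the other 3 titles end in m, so sex is not balanced between the groups. The sex-linked values argue against the same animal as the source of both SFR KO libraries. They do not settle this for the WT libraries.

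Of 13631 genes tested, 814 were higher and 567 lower in SFR KO by limma at an adjusted p under 0.05. Among these, 372 rose and 152 fell by more than 2-fold. The quasi-likelihood test of edgeR called 891 higher and 584 lower, 1367 of them shared with limma. The authors' deposited results called 931 genes higher and 647 lower, and 1266 of the genes called by limma were called there, all 1266 in the same direction. Across genes, log2 values correlated at 0.994 within WT, 0.992 within SFR KO and 0.977 to 0.980 between the groups; genes are not independent replicates. Below, rose and fell are used of genes called by limma. Leaving out WT replicate 1 reduced the calls to 356 higher and 236 lower, and leaving out WT replicate 2 to 377 and 373. Without a mean-variance trend limma called 192 higher and 112 lower, among them 6 NKT1 genes lower and 2 higher, 1 NKT17 gene higher and 0 lower, and 0 proliferation genes.

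Among the rises eligible under the naming rule, the largest was that of Gpr35, a G protein-coupled receptor. It rose from 5.40 ± 6.12 to 620 ± 276 normalized counts (SD, n = 2 each), with low WT values of 9.72 and 1.07. Ascl1, a transcription factor of neural precursors, rose to 479 ± 37.7, a log2 fold change of 5.52 ± 0.33 (SE). Pltp, a phospholipid transfer protein, rose from 125 ± 12.2 to 2186 ± 811. Npnt, an extracellular matrix ligand of integrins, rose from 60.6 ± 34.0 to 1304 ± 570, and Vax2, a homeobox factor, from 61.2 ± 16.6 to 1065 ± 195. The other genes among the 13 rises named by the rule fixed in advance were Urah, Garem, Pkdcc, Rnf150, Pgbd5, Capn11, Flrt2 and Glyat, with log2 fold changes of 3.90 to 6.14. Among the falls eligible under the naming rule, the largest was that of Rab27b, a small GTPase of secretory granules. It fell from 170 ± 39.3 to 6.24 ± 1.16, a log2 fold change of -4.55 ± 0.31 (SE). Styk1, a receptor-like kinase, fell from 7537 ± 64.6 to 1956 ± 554. Pygl, a glycogen phosphorylase, fell from 795 ± 115 to 142 ± 51.6, and Tjp1, a tight junction protein, from 1349 ± 236 to 351 ± 116. The other falls named by that rule were Igkc, Akr1c18, Hic1, Nmur1, Ifitm3, Acoxl, Gpr34, Ifitm1 and Hrh4, with log2 fold changes of -3.13 to -1.99. Reads of Ifitm1 and Ifitm3 can be shared with related genes. Adjusted p-values reached 0.186 for Capn11 and 0.0530 for Nmur1 without WT replicate 2, 0.0544 for Hic1 without WT replicate 1, and 0.0582 and 0.0885 for Ifitm1 without each WT library. With robust eBayes they were 0.0562 for Urah, 0.233 for Capn11 and 0.0750 for Akr1c18, and with DESeq2 0.328 for Capn11.

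Genes of the NKT1 program, the T-bet-dependent subset that makes interferon gamma, were mostly lower in SFR KO. Of 32 tested members 17 fell and 4 rose (21 and 4 adjusted over the list alone), and camera placed the list below other genes (adjusted p = 4.5e-08, median log2 fold change -0.53; adjusted p = 0.54 with an estimated correlation). Tbx21, which encodes T-bet, fell from 13153 ± 633 to 7688 ± 164. Gzmb, a granzyme of cytotoxic granules, fell from 25956 ± 505 to 11588 ± 1003, Nkg7 from 29080 ± 788 to 14841 ± 1208, and the lectin-like receptor Klrd1 from 7070 ± 105 to 3505 ± 232. Klra7, an Ly49 receptor whose reads can be shared with near-identical copies, rose from 1115 ± 213 to 3485 ± 23.5. Ifng had 946 ± 378 in WT and 630 ± 30.6 in SFR KO (adjusted p = 0.23; 0.0215 without WT replicate 1). The NK cell marker list, which shares 5 of its 11 genes with NKT1, went both ways, with 3 higher and 4 lower (3 and 4 adjusted over the list alone) and a camera adjusted p of 0.999. Without either WT library these counts were 2 and 2. Ncr1, an activating NK receptor, rose from 29.9 ± 9.33 to 276 ± 27.6, whereas the pore-forming protein gene Prf1 fell from 5385 ± 570 to 2307 ± 551 and Klri2 from 2320 ± 168 to 834 ± 238.

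NKT17 genes, those of the subset that makes IL-17, were mostly higher in SFR KO. Of 21 tested members 13 rose, 0 fell and 8 did not pass the test (15 and 1 adjusted over the list alone), with a median log2 fold change of 0.97 and a camera adjusted p of 4.5e-08 (adjusted p = 0.54 with an estimated correlation). Rorc, the lineage factor of IL-17-producing cells, went from 1979 ± 333 to 6590 ± 2697 (adjusted p = 0.0050; 0.0584 without WT replicate 2 and 0.0771 with robust eBayes). The IL-23 receptor gene Il23r rose from 1087 ± 247 to 5057 ± 1687, Sox13 from 997 ± 77.0 to 4254 ± 1275, Blk from 3317 ± 324 to 14156 ± 5025 and Maf from 13553 ± 1127 to 23211 ± 667. Cd44, Itgb7, Rora and Il7r, named after their values were seen, had log2 fold changes of -0.34, -0.23, -0.14 and -0.06, with adjusted p-values of 0.070 to 0.87. SFR KO replicate 2 lay above replicate 1 by a median of 0.63 on the log2 scale over this list. Robust eBayes called 7 members higher and 0 lower, and DESeq2 called 14 higher and 1 lower. The called members numbered 6 without WT replicate 1 and 5 without WT replicate 2. Markers of gamma-delta T cells rose as well, 7 of 8 tested (7 adjusted over the list alone; camera adjusted p = 2.0e-07; adjusted p = 0.54 with an estimated correlation). The NKT17 list also holds 2 of its genes, Sox13 and Blk. Cd163l1 rose from 688 ± 93.0 to 1736 ± 131 and Tcrg-C2 from 7637 ± 51.4 to 12114 ± 731. Without the shared genes, the NKT17 list kept a mean log2 fold change of 0.86 (camera adjusted p = 2.1e-06; adjusted p = 0.54 with an estimated correlation).

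The NKT2 list, the subset that makes IL-4, had 2 members higher and 2 lower of 16 (2 and 2 adjusted over the list alone), with a camera adjusted p of 0.77, and 1 and 1 without WT replicate 1. Its median log2 fold change was 0.07 and its mean -0.02. Zbtb16, which encodes the iNKT lineage factor PLZF, rose from 11905 ± 2007 to 20926 ± 1481. The costimulator gene Icos rose from 35968 ± 486 to 51507 ± 2856, the IL-4 receptor gene Il4ra fell from 5462 ± 770 to 2012 ± 289, and Ltb fell from 25010 ± 750 to 16309 ± 1784. Icos and Ltb had adjusted p-values of 0.0582 and 0.0544 without WT replicate 1. Gata3 had 10579 ± 490 in WT and 10559 ± 605 in SFR KO (adjusted p = 0.99), Il4 768 ± 73.6 and 808 ± 111 (0.83), and Il17rb 3547 ± 458 and 3421 ± 630 (0.86).

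**Figure D2:**
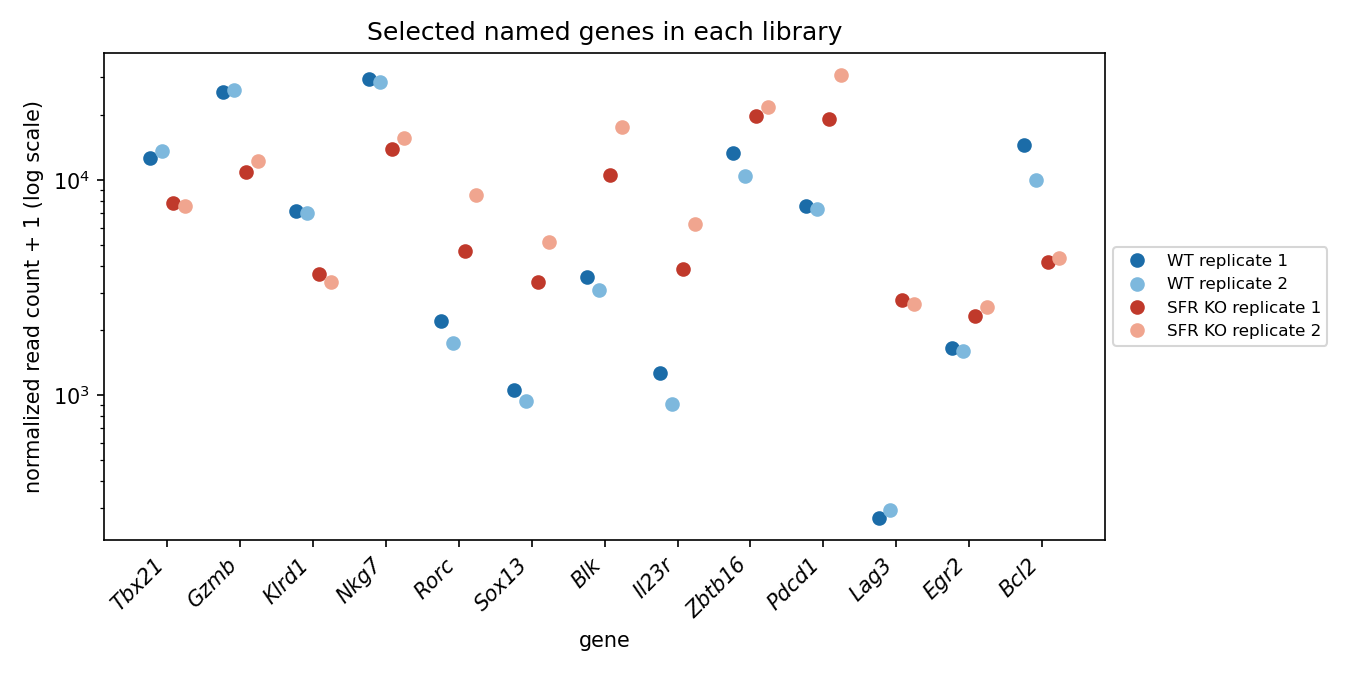
Normalized read count + 1 (vertical log axis) of 13 named genes (horizontal axis), 1 point per library. All 13 were genes called by limma, and their WT and SFR KO points do not overlap. Genes named in advance but not called, such as Gata3 and Il4, are not shown. Lag3 lies near 280 in WT and 2710 in SFR KO.

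Genes induced by TCR signalling moved in both directions, with 7 of 29 higher and 4 lower (12 and 7 adjusted over the list alone; camera adjusted p = 0.47). The counts were 4 higher and 3 lower without WT replicate 1, and 7 and 7 without SFR KO replicate 2. Egr2 and Egr3, transcription factors downstream of the TCR, rose from 1634 ± 37.9 to 2451 ± 164 and from 1977 ± 70.7 to 3203 ± 26.2. Bhlhe40 fell from 3780 ± 440 to 1367 ± 309 and Cd40lg from 6918 ± 218 to 4486 ± 239. Among inhibitory receptors and associated genes, 4 of 12 rose and 2 fell (4 and 4 adjusted over the list alone), with a median log2 fold change of -0.04, a mean of 0.22 and a camera adjusted p of 0.77. Lag3 rose from 280 ± 17.5 to 2710 ± 66.7, a log2 fold change of 3.27 ± 0.11 (SE). Pdcd1, which encodes PD-1, rose from 7459 ± 186 to 25002 ± 8133 and Tox from 6469 ± 731 to 11566 ± 307, whereas Tigit fell by 1.72 on the log2 scale. Immediate early and heat shock genes were lower, with 5 of 20 falling and 0 rising (10 and 0 adjusted over the list alone; camera adjusted p = 0.00011; adjusted p = 0.54 with an estimated correlation). Dusp1 fell from 10186 ± 3300 to 2742 ± 597 and Klf6 from 9284 ± 368 to 5552 ± 323. The WT libraries differed over this list, WT replicate 2 being higher by a median of 0.34 on the log2 scale. Without WT replicate 2, 2 members were lower, without WT replicate 1, 8. Without SFR KO replicate 1, 7 were lower and 2 higher, and without SFR KO replicate 2, 11 and 1.

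Genes of stage 0 and early iNKT precursors were higher as a list, with 9 of 18 rising and 3 falling (10 and 4 adjusted over the list alone; camera adjusted p = 0.0334; adjusted p = 0.54 with an estimated correlation; 0.0741 without WT replicate 2). Myb, a factor of progenitor cells, rose from 2357 ± 209 to 6135 ± 90.3, Sox4 from 1214 ± 49.5 to 2876 ± 355 and Hivep3 from 4510 ± 660 to 10243 ± 83.9. Ccr9, a chemokine receptor of thymocytes, fell from 5904 ± 469 to 3079 ± 244. Genes of proliferation rose in 17 of 33 members, with 0 lower (31 and 0 adjusted over the list alone; camera adjusted p = 6.0e-14; adjusted p = 0.54 with an estimated correlation), and all 33 had a positive fold change. Mki67 went from 6301 ± 595 to 12942 ± 4233 and Stmn1 from 6454 ± 701 to 10950 ± 2225. Without WT replicate 1 their adjusted p-values were 0.0792 and 0.108, and without WT replicate 2 that of Mki67 was 0.116; with robust eBayes it was 0.0712. SFR KO replicate 1, the library with Xist reads, lay above replicate 2 by a median of 0.53 over this list. On all libraries, robust eBayes called 5 members higher, limma without a filter 11 and DESeq2 26. The members called numbered 0 without WT replicate 1, 1 without WT replicate 2, 8 without SFR KO replicate 1 and 31 without SFR KO replicate 2.

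Of 32 tested genes of the Bcl-2 family and death receptors, 2 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.26), or 1 and 3 without WT replicate 1. Bcl2, an inhibitor of apoptosis, fell from 12290 ± 3228 to 4242 ± 141, the death ligand gene Fasl from 4765 ± 1111 to 1577 ± 236 and Tnfrsf1a from 4450 ± 325 to 2733 ± 25.5. Bcl2a1a, which shares reads with near-identical copies, rose to 208 ± 90.6, a log2 fold change of 3.56. Bcl2l11, which encodes the death-promoting protein BIM, had 4613 ± 2035 in WT and 4028 ± 293 in SFR KO (adjusted p = 0.83; 0.0350 without WT replicate 2). Interferon-response genes were lower in 9 of 32 members and higher in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 2.1e-08; adjusted p = 0.54 with an estimated correlation). Ifitm3 fell from 535 ± 84.6 to 121 ± 12.0, Ifit3 from 4080 ± 135 to 2446 ± 146 and Isg20 from 3213 ± 91.4 to 2091 ± 105. The members called numbered 3 without WT replicate 1.

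For egress and homing receptors 2 of 21 rose and 5 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0128; adjusted p = 0.54 with an estimated correlation; 0.116 with quantile scaling). The integrin gene Itga4 rose from 3095 ± 44.8 to 10499 ± 669, whereas Cxcr6 fell from 31828 ± 47.7 to 14212 ± 1266, Cxcr3 from 19531 ± 300 to 10911 ± 304 and Itga1 from 8172 ± 601 to 3984 ± 500. Cytokines and chemokines went both ways, 3 of 20 higher and 4 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.51), or 2 and 2 without WT replicate 2. Tnfsf11 rose from 1279 ± 145 to 2190 ± 36.0 and Il21 from 121 ± 39.6 to 371 ± 59.9, and Ccl5 fell from 3581 ± 64.6 to 2244 ± 260. Among SAP adaptors and signalling partners of the SLAM receptors, 1 of 13 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.27). Pak1 rose by 0.77 on the log2 scale, and Plcg1 and Ptpn6 fell by 0.41 and 0.43 on the log2 scale; each lost its call without at least 1 library, at adjusted p-values of 0.0634 without WT replicate 1 for Pak1, 0.0731 without WT replicate 1 and 0.0574 without SFR KO replicate 1 for Plcg1, and 0.124 without WT replicate 2 for Ptpn6. Sh2d1a, which encodes SAP, had 3038 ± 311 and 3159 ± 215 (adjusted p = 0.80). Glycolysis genes were called in 1 upward and 2 downward cases of 17 (2 and 2 adjusted over the list alone; camera adjusted p = 0.29), or 0 and 1 without WT replicate 1 and 0 and 0 without WT replicate 2.

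**Figure D3:**
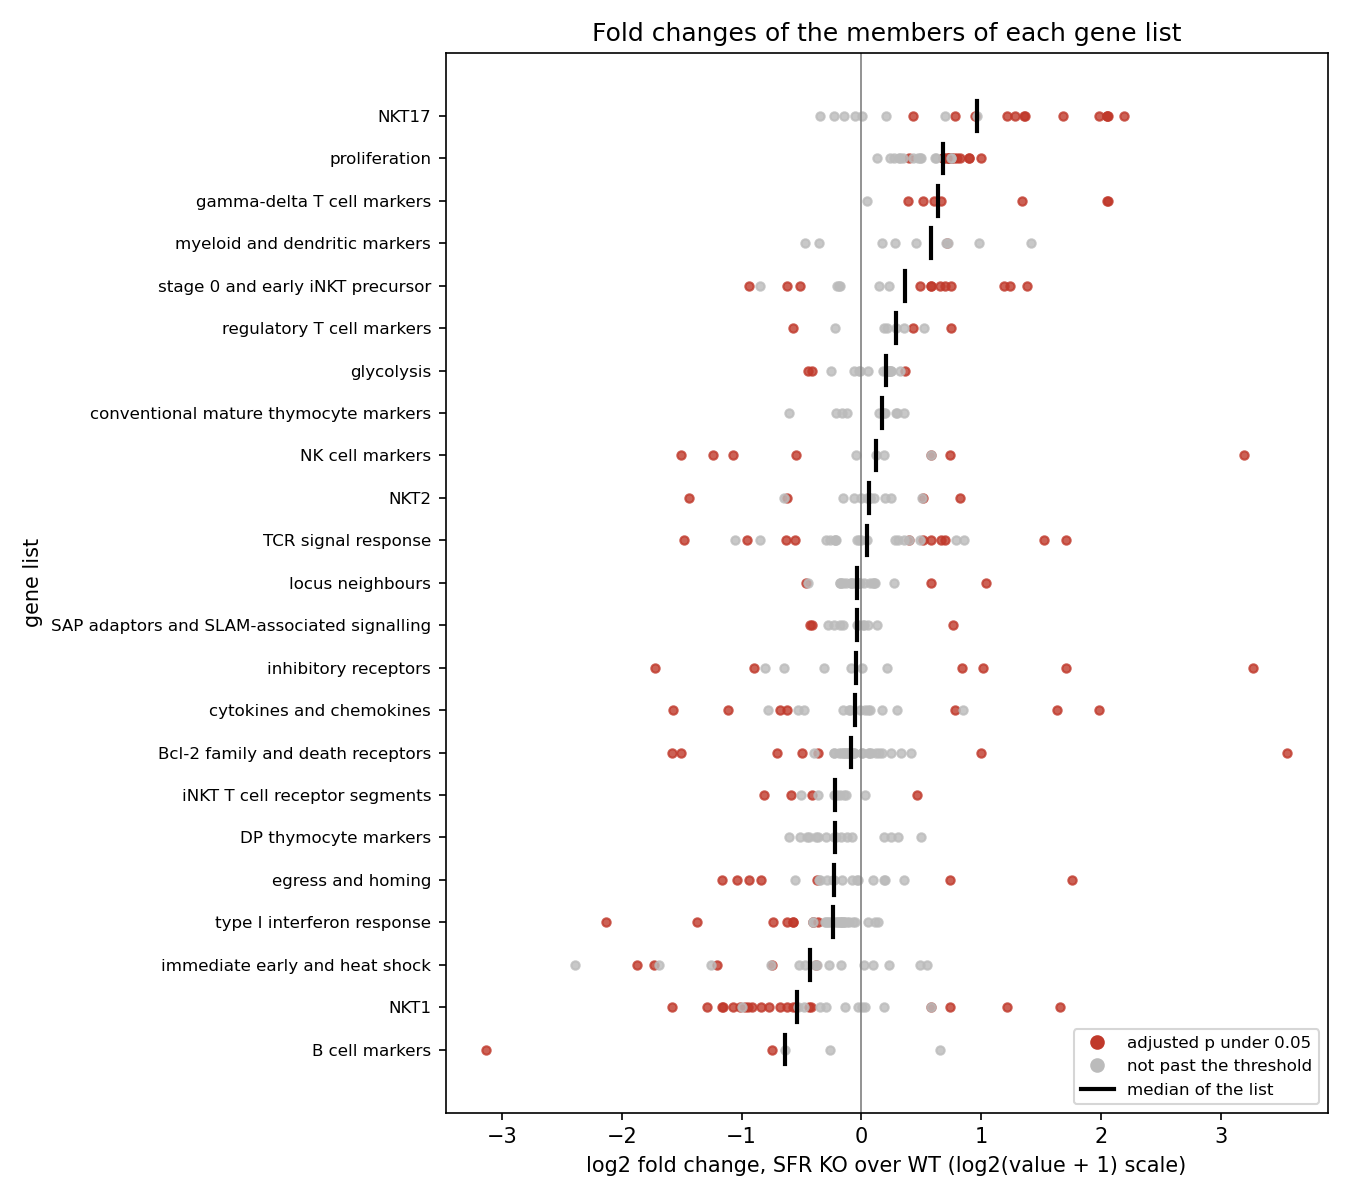
Log2 fold change (SFR KO over WT, horizontal axis) of every tested member of 23 gene lists (vertical axis), with genes past the threshold in red and the list medians as black bars. The NKT17 median lies at 0.97 and the NKT1 median at -0.53.

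The list of iNKT T cell receptor segments (TCR segments below) also holds constant genes and CD3 chain genes, so it does not measure segment usage alone. An alpha variable segment in it, Trav11d, fell from 745 ± 3.82 to 496 ± 46.3 (limma adjusted p = 0.026). Its log2 fold change was -0.49 without SFR KO replicate 1 and -0.68 without SFR KO replicate 2. The list was lower, with 3 of 13 falling and 1 rising (3 and 1 adjusted over the list alone, camera adjusted p = 0.00928, and 0.54 with an estimated correlation). That call was lost without WT replicate 2 (0.0568), without SFR KO replicate 1 (0.0864) and with quantile scaling (0.0583), and 0 members were called without WT replicate 1. Trbv29 went from 4452 ± 457 to 6131 ± 36.3 (adjusted p = 0.023; 0.0853 without WT replicate 1). Trbv1 went from 2150 ± 33.1 to 1235 ± 253 (0.011; 0.0712 and 0.0727 without each WT library). Trac, the constant segment of the alpha chain, went from 35378 ± 2134 to 26728 ± 3030 (0.045; 0.185 and 0.0964 without each WT library and 0.269 without SFR KO replicate 1). Of B cell markers 2 of 5 fell (2 adjusted over the list alone; camera adjusted p = 0.0334; adjusted p = 0.54 with an estimated correlation). Igkc fell from 109 ± 38.0 to 11.4 ± 3.85 and Ighm from 10377 ± 371 to 6186 ± 315. Cd22 went from 120 ± 35.6 to 74.9 ± 0.167 and Cd79b from 71.4 ± 0.743 to 117 ± 41.5, neither called (limma adjusted p = 0.17 and 0.19). Ighm stood far above Cd22 and Cd79b, so the list is not read here as a share of B cells. The list lost its call without WT replicate 2 (0.0571), with a filter at a mean of 1 (0.0881) and without a filter (0.135).

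Other lists were not called. Regulatory T cell markers had 2 of 9 higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.31; 1 and 1 without either WT library), with Ikzf2 rising from 4331 ± 477 to 7279 ± 447 and Tnfrsf18 falling from 4265 ± 220 to 2872 ± 64.9. Of 10 myeloid and dendritic markers Cd74 alone rose, from 352 ± 6.06 to 578 ± 31.8 (1 adjusted over the list alone; camera adjusted p = 0.11; 0.0298 without SFR KO replicate 1 and 0.0310 without WT replicate 2). Without each WT library Cd74 had an adjusted p of 0.0722 and 0.0589 and 0 markers were called, and without SFR KO replicate 1 there were 3. By limma 0 of 16 double-positive thymocyte markers, 0 of 10 markers of conventional mature thymocytes, 0 of 3 epithelial markers and 0 of 15 mitochondrially encoded genes were called (0 in each adjusted over the list alone). At an unadjusted p under 0.05 there were 3 higher and 3 lower, 2 and 1, 1 and 1, and 0 and 0 of these. Counts called by edgeR were 0 for all 4 lists, and DESeq2 called 1 double-positive marker lower. Camera adjusted p-values for these lists were 0.31, 0.77, 0.78 and 0.77. Mitochondrial genes were highest in SFR KO replicate 1, as for mt-Atp8 with 23057 normalized counts against 10055 in replicate 2, and their list was called without SFR KO replicate 2 (0.0166), with 2 members higher; 1 double-positive marker was then higher and 2 lower. Of 23 genes neighbouring the deleted locus 2 rose and 1 fell (2 and 1 adjusted over the list alone), with a median log2 fold change of -0.03, a mean of 0.01 and a camera adjusted p of 0.77. Fcer1g, at 171229572 to 171234365 on chromosome 1, rose from 2837 ± 210 to 4250 ± 209. Atp1a2 and Pea15a had log2 fold changes of 1.04 and -0.46 and adjusted p-values of 0.0295 and 0.0227, which reached 0.138 and 0.0999 without WT replicate 1, and for Pea15a 0.0725 and 0.120 without WT replicate 2 and SFR KO replicate 1. With an estimated correlation 0 of the 25 lists were called, none at an unadjusted p under 0.05. The rotation test fry called 0 lists in 1 direction (9 at an unadjusted p under 0.05) and 20 for change in either direction; fry does not compare a list with other genes.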

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

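All alternatives below were planned except the 2 lists with members left out. Across 30 recomputed counts, 24 stayed within 1.5 times the main value. Without a mean-variance trend limma called 192 genes higher and 112 lower, 273 of the 304 shared with the main calls. Leaving out single libraries gave 356 to 996 higher and 236 to 682 lower, the lowest without WT replicate 1 and the highest without SFR KO replicate 2; these fits rest on 3 libraries, and the lone library of a group is assumed to vary like the other group. Of 135 named genes, 0 called genes reversed, and 63 of 104 calls were lost without the trend; the cause was not tested. Robust eBayes lost 6 (Urah, Capn11, Akr1c18, Rorc, Mki67 and Junb), and Capn11 was also lost with a pseudocount of 0.5, a filter at a mean of 1, no filter and DESeq2. No paired analysis was possible because the titles of the groups share only 1 number.

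Mean log2 fold changes of the 10 called lists were -0.40 for NKT1, 0.98 for NKT17, 0.25 for stage 0, 0.62 for proliferation, -0.34 for interferon response, -0.16 for egress, -0.64 for immediate early genes, 0.96 for gamma-delta markers, -0.82 for B cell markers and -0.25 for TCR segments. These means do not depend on the list test. Each list lost its call with an estimated correlation (adjusted p = 0.54). Egress and B cell markers had estimated correlations of -0.020 and -0.187, below the preset 0.01. Their unadjusted camera p still went from 0.0041 to 0.088 and from 0.0134 to 0.128. The other called lists had estimated correlations above 0.01, from 0.036 for stage 0 to 0.953 for proliferation, with 0.567 for NKT17. For proliferation and NKT17 the small p-values therefore rest on a preset correlation far below the estimate. Their unadjusted camera p went from 2.4e-15 to 0.246 and from 5.3e-09 to 0.21. None of the 10 lists was called by fry's directional test (0.0665 to 0.263). That test asks whether a list changed at all and not whether it differs from other genes. The median log2 fold change of all tested genes was near 0 (-5.4e-05), so the answers bear on each other here. Unadjusted fry p was 0.076 for NKT17, 0.147 for proliferation and 0.073 for immediate early genes. It was under 0.05 for the other called lists. Quantile scaling gave -0.13 for egress and -0.24 for TCR segments, neither called (adjusted p = 0.116 and 0.0583). B cell markers stood at -0.54 with a filter at a mean of 1 and at -0.40 without a filter. Leaving out 1 library gave 0.36 to 0.87 for proliferation (without SFR KO replicates 1 and 2), -0.88 to -0.40 for immediate early genes (without WT replicates 1 and 2), 0.21 to 0.29 for stage 0, -0.92 to -0.72 for B cell markers, -0.26 to -0.24 for TCR segments, 0.18 to 0.75 for myeloid markers and -0.11 to 0.34 for mitochondrial genes. The last 2 lists were called in 2 and 1 of these fits, and inhibitory receptors with DESeq2 (0.22, adjusted p = 0.0063). Lists without shared or near-identical members were called at the preset correlation, at 0.86 for NKT17 and -0.55 for NKT1, and not with an estimated correlation (adjusted p = 0.54). The reduced NKT1 list left out the Klra genes, among them Klra7 and Klra1, which rose (log2 fold changes of 1.66 and 1.21), and Klra9 (-0.35, not called). Its mean moved further below 0 through the members left out.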

Other observations

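The gene families, the beta-chain usage and all tests of explanations here were chosen after the results were seen, except the test of the genes near the locus and the standard error test of Cd48 and Slamf7. Among 363 families of tested genes sharing a symbol stem, 7 were called by camera at the preset correlation and 0 with an estimated correlation (adjusted p = 0.997 for each). All 9 tested transcripts of the Gimap cluster on chromosome 6 were lower in SFR KO, with a median log2 fold change of -0.89. They are genes of GTPases of lymphocyte survival and Gimap1os, an opposite-strand transcript overlapping Gimap1, whose reads are not independent of that gene. Gimap6 fell from 26212 ± 693 to 11737 ± 990 normalized counts (SD, n = 2), Gimap7 from 1041 ± 241 to 284 ± 72.8 and Gimap3 from 10530 ± 2081 to 4308 ± 982. Reads can be shared within this family. Symbols starting with Rpl and Rps had medians of -0.21 and -0.22, with 0 of 90 and 7 of 72 called lower; these stems hold ribosomal protein genes but also pseudogenes and, for Rps, kinases such as Rps6ka1. Joining segments of the TCR alpha locus had a median of -0.57, with 3 of 27 called lower. Of symbols starting with Kif and Cdca, 5 of 29 and 3 of 7 were called higher and 0 lower.

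For some beta-chain variable segments of the T cell receptor (Trbv), the share of Trbv reads differed between the WT and SFR KO libraries. These are shares of reads and not of cells, and a larger share of 1 segment lowers the shares of the others. Trbv29 made up 24.2% and 25.9% of Trbv reads in the WT libraries and 38.8% and 34.5% in the SFR KO libraries. In mean ± SD (n = 2 each) Trbv1 went from 12.1% ± 0.481 to 7.45% ± 2.18, Trbv13-1 from 11.2% ± 0.553 to 5.96% ± 0.917 and Trbv13-3 from 6.65% ± 0.00877 to 2.96% ± 0.505. Trbv13-2 stood at 32.8% ± 0.648 and 31.8% ± 3.93. By limma Trbv13-1 and Trbv13-3 fell (adjusted p = 0.0010 and 0.00077); reads of the Trbv13 segments can be shared. Trbv19 made up 5.42% of reads in SFR KO replicate 2 (exact 95% interval 5.08% to 5.78%) and under 1% in each other library, and Trbv5 3.75% in SFR KO replicate 1 (3.48% to 4.04%).

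Of 21 NKT17 genes 13 were called higher in SFR KO (adjusted p = 0.54 for the list with an estimated correlation), and 3 of 6 tested Tcrg-V segments of the gamma chain were called higher too, with log2 fold changes of -0.28 to 1.12 over the 6 (camera adjusted p = 0.315 for that family), although the sort required tetramer binding, which most gamma-delta T cells lack. Such cells would bring delta-chain reads, but the Trdv reads were 26 and 20 in WT and 21 and 29 in SFR KO. The upper 95% counting limit of the SFR KO mean less the lower limit of the WT mean was 0.3226% of the rise of Rorc. With the segments that the alpha and delta chains share it was 0.496%. This bound covers counting error only, and the Trdv reads that a gamma-delta cell gives per Rorc read were not measured. The lack of a clear rise in Trdv reads argues against gamma-delta cells as the source of the Rorc rise. The called gamma-chain segments stay unexplained, and the delta constant gene was not among the genes analysed here. Nor was the NKT17 change seen only in the library with Xist reads. The median log2 fold change of the list was 1.398 without SFR KO replicate 1 and 0.74 without SFR KO replicate 2. Each value rests on 1 SFR KO library. Replicate 2 lay above replicate 1 over this list, so a higher median without replicate 1 followed from that gap. A larger share of NKT17 cells among sorted iNKT cells, or more expression per cell, may account for the NKT17 change. Neither was tested, and sex is not balanced between the groups.

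Genes near the deleted locus might differ through flanking DNA of another strain or through a local effect of the deletion. Within 5 Mb of the locus, 6 of 66 tested genes were called (9.09%), against 1364 of 13456 elsewhere (10.1%). The odds ratio by Fisher's exact test was 0.8865 (95% interval 0.312 to 2.05), so an excess of up to that bound cannot be told apart from none with 66 genes.

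In the authors' deposited table the log2 fold changes of Ly9, Cd48 and Slamf7 were -1.66, -0.76 and -0.76, although these genes had 0.0543% or less of their WT level in SFR KO; of 39 genes with a mean over 100 and a log2 ratio beyond 3 in size, 8 had a deposited value under 1 in size, Gpr35, Urah, Pkdcc and Glyat among them. Remaining reads of Cd48 and Slamf7 (0.05431% at most) argue against incomplete loss. DESeq2 with a fold change prior centred on 0 came within 0.02 of the deposited value for 21105 of 21111 genes, and gave -1.659 for Ly9 with its gene-wise dispersion, against -11.2 without the prior, consistent with shrinkage of a gene with an outlying dispersion. For Cd48 and Slamf7 the gene-wise dispersion of this newer version left -7.629 or lower, so that estimate did not give the deposited values. A dispersion of 0.539 gave both deposited fold changes with standard errors within 0.0002011 of the deposited ones, so shrinkage under an inflated dispersion may account for them too; how it arose stays open.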
